A study of Homo sapiens with 22 samples.

How the data were processed

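DNA methylation was measured in 12 libraries and RNA in 10, from biopsies of PTCL before (C1D-6) and after (C1D1) CC-486. The labels name the same case at both times, so each case formed a pair: 6 pairs for methylation, of which case 1 is blood and cases 2 to 6 are tissue, and 5 pairs for RNA, cases 2 to 6. There were no untreated samples, so time and treatment go together. The pairs were checked on the values and are given here as counts. At sites specific to a case, 6 of 6 after-treatment methylation libraries were closest to the before-treatment library of their own case, and 5 of 6 were over all sites. For RNA, 4 of 5 were closest to their own, with a correlation of deviations across genes of 0.0578 to 0.743.

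The methylation libraries were made by RRBS with single reads of 100 cycles, per the labels. Per the submitters' processing notes, the authors aligned them with Bismark to the human genome build hg19, in versions not stated. The deposited tables give, for each cytosine, the count of reads covering it and the percent of these reads that were methylated. The lowest coverage in each table was 10, and coverage times percent gave whole reads, with a largest deviation of 2.2e-11. The deposited tables also mark cytosines in regions of poor mappability with 0 or 1. For RNA, the deposited table holds 20062 genes in log2 units, and 2 to the power of the value, minus 1, summed to 1000000 in each column, so the values are log2(TPM + 1). The authors used kallisto and hg19, per the submitters' processing notes, and the annotation, the summing to genes and any gene filter are not stated. Of the gene names, 18490 matched the Ensembl symbol table and 18373 matched a RefSeq symbol.

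Total coverage, summed over cytosines, was 133191428 to 546879062 per methylation library, with 133191428 before and 428136731 after in case 2. Each level rests on a coverage of at least 10 reads. Since reads without molecular identifiers are not independent molecules, tests on reads within a pair cover at most the counting error of reads. The read depth of the RNA libraries is unknown, so no counting error is given for TPM.

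Methylation levels were averaged over the 4246614 autosomal CpG cytosines covered in all 12 libraries, and paired differences were tested with an exact two-sided sign-flip test (64 assignments, smallest p 0.0313, or 0.0625 with 1 case left out). Sites were classed by their mean level before treatment in the other 5 cases, so that a case did not choose its own class, and by the number of other covered CpG positions within 100 bp, in 3 parts split at 5 and 13. Benjamini-Hochberg adjustment was within each family of 3 classes. Within a pair, each cytosine with coverage of at least 10 in both libraries was tested with Fisher's exact test, and called at an adjusted p under 0.01 and a difference of at least 25 percentage points. These calls compare 2 libraries, and the pairs are the replicates. Windows of 1 kb with at least 3 CpGs covered in every library were tested with a quasi-binomial logistic model of methylated and unmethylated counts, 0.5 added to both, with the case as a block and the dispersion moderated with limma's squeezeVar.

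Expression was tested with limma (trend and robust settings) on log2(TPM + 1) for the 14571 genes with a mean of at least 1 TPM, with the case as a block, and genes were called at an adjusted p under 0.05. The plan had a branch for TPM and another for values on a log scale. The deposited values are log2(TPM + 1), the scale the first branch produces, so both branches test the same values, and the filter of the first was kept. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. The 30 lists covered what a hypomethylating agent acts on and the cell types a lymphoma biopsy can hold, and 28 had a measured member; the mitochondrially encoded genes and the replication-dependent histones had none in the table. Genes of the immunoglobulin and T-cell receptor segments were not named. The genes named are the 10 per direction with the smallest unadjusted p among those that moved one way in all 5 pairs, since none passed, the 3 members of smallest p of each list past the camera test, and DNMT1, DNMT3A, DNMT3B, UHRF1, TET2, MKI67, CD3E, MS4A1, CD68 and ISG15. VSIG4, KRT5, COL1A1 and NFKBIA fall outside this rule and were chosen after their values were seen. Windows were to be named only if they passed.

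The comparisons, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives were another coverage minimum, window width or test, other averaging and site sets, quantile normalization, other filters and pseudocounts, protein-coding symbols alone, no pairing or block, and each case left out in turn. Chosen after the data were seen were the thinning of each pair to 20 reads per site, leaving out marked regions and CpGs whose strands disagree, leaving out haemoglobin, immunoglobulin and keratin genes with rescaling, leaving out pairs 2 and 3, and, for lists, the settings without trend and robust, with a pseudocount of 0.1 and with protein-coding symbols. No annotation of hg19 was used here, so the planned classes by CpG island, promoter, exon and intron, and the comparison of promoter methylation with expression, were not run.

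The tests were tried on simulated data. With 5 pairs, limma recovered 23.9% of genes with a log2 change of 1, 64.2% at 2 and 83.3% at 4, with 3 false calls among 14265 genes. Those genes varied independently, and changes had the same size in each case and were placed in genes above a low level alone. In the real data the genes of a list moved together, with estimated correlations of up to 0.927, and changes differed by case. Neither the shares recovered nor the 3 false calls carry over to the real genes. The test within a pair recovered 16% of cytosines that differed by 25 points and 93% at 50 points, with 0 false calls among 200000. Those simulated reads were independent and of equal coverage at all sites and in both libraries, with losses placed at methylated sites alone. Real reads were not so, with a median coverage of 26 before and 79 after in pair 2. Neither the shares recovered nor the 0 false calls carry over to the real calls. The window model recovered 29.9%, 73.1% and 97.0% of windows that differed by 10, 20 and 40 points, but 29 of its 162 calls were false (17.9%) and 7.11% of unchanged windows had an unadjusted p under 0.05, so it was too liberal on the simulated data. Of the real windows, 3.40% had an unadjusted p under 0.05. The simulated windows varied independently, with losses placed in mostly methylated windows alone, so these shares do not carry over to the real windows. The window simulation was revised once, since noise had first been added to 1 of the 2 arms, and the test itself was not changed. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.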

Results

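Biopsies of peripheral T-cell lymphoma (PTCL), a group of cancers of mature T cells, were profiled before and after CC-486, an oral form of azacitidine. Azacitidine is a cytidine analogue that is built into nucleic acids and traps DNA methyltransferases, the enzymes that keep CpG methylation in place when DNA is copied. The 22 libraries comprised 12 of DNA methylation from 6 cases and 10 of RNA from 5 of these cases, with 1 library per case at cycle 1 day -6 (before) and 1 at cycle 1 day 1 (after). Case 1 gave blood, and cases 2 to 6 gave tissue. Methylation was read by reduced representation bisulfite sequencing (RRBS), which samples restriction fragments rich in CpGs. The RRBS libraries listed 4593200 to 6410669 cytosines at a median coverage of 25 to 74 reads. Coverage summed over these cytosines was 133191428 to 546879062, where a read counts once at each cytosine it covers, so these are not numbers of reads. The RNA libraries had 13291 to 14279 genes at a level of 1 TPM (a share of transcripts adjusted for length) or more, and their read depth is unknown.

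The first comparison asked whether DNA methylation differed after CC-486. Over the 4246614 autosomal CpG cytosines covered in all 12 libraries, the mean methylation level was 43.0% ± 0.648 (SD, n = 6) before and 42.8% ± 1.03 after. The paired difference was -0.194 percentage points ± 0.710 (SD), smaller than its spread, and it was negative in 4 of 6 cases (exact two-sided sign-flip test, p = 0.5625). With 1 case left out it lay between -0.418 (without case 3) and -0.0579 (without case 2). Cases 1, 2, 4 and 6 differed by -0.737, -0.876, -0.699 and -0.0681 points. Cases 3 and 5 differed by 0.926 and 0.289 points. With the 12 libraries permuted without the pairing by case, the difference of -0.194 had an exact p of 0.745. Methylated reads over all reads, in place of the mean over cytosines, gave a difference of 0.132 points (exact two-sided p = 0.781). At 12.1% of the CpGs read on both strands the strands differed by over 20 points, and without these CpGs the mean level was 42.5%.

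**Figure D1:**
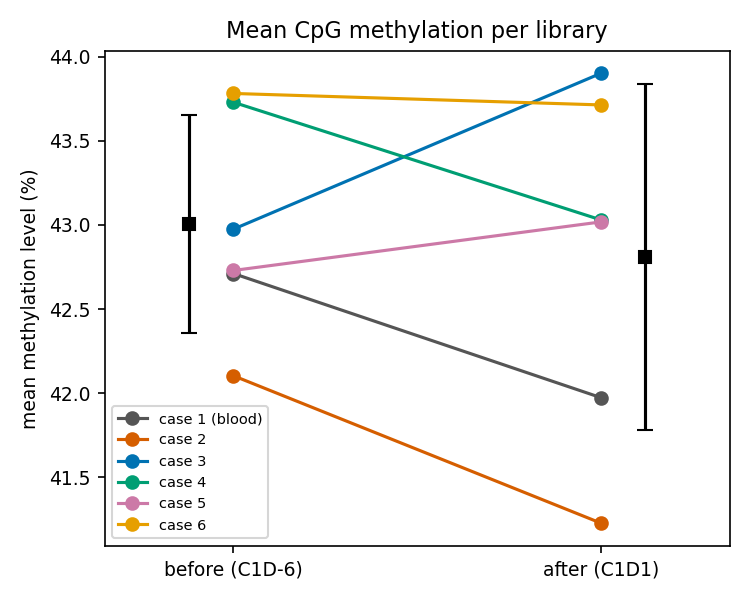
Mean CpG methylation level (percent, vertical axis) of each library before (C1D-6) and after (C1D1) treatment, with a line per case and, beside them, the mean and SD of the 6 libraries (black squares). The lines of cases 1, 2, 4 and 6 slope down and those of cases 3 and 5 slope up.

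Methylated and unmethylated parts of the sampled genome were compared apart, since the drug can act on methylated sites alone. Cytosines above 80% methylation in the other cases went from 90.4% before to 90.1% after, a difference of -0.329 points ± 1.40 (SD, n = 6; exact two-sided p = 0.5625). Those between 20% and 80% went from 57.9% to 57.8%, a difference of -0.147 points ± 1.59 (SD, n = 6; exact two-sided p = 0.84375). Those below 20% differed by -0.108 points ± 0.274 (SD, n = 6; exact two-sided p = 0.5), and the adjusted p over these 3 classes was 0.84375 for each. The difference below 20% was negative in 2 of 6 cases and ran from -0.152 to -0.0334 with a case left out. CpG-sparse regions, with 5 or fewer other covered CpG positions within 100 bp, had 69.8% before and 69.6% after. Regions of intermediate density had 46.6% and 46.3%, and CpG-dense regions, which were not matched to annotated CpG islands, had 7.53% and 7.39%. Their differences of -0.173, -0.266 and -0.143 points had exact two-sided p of 0.6875, 0.5 and 0.5 (6 pairs, adjusted p = 0.6875 for each). With a case left out the difference ran from -0.561 to -0.0518 at intermediate density and from -0.287 to -0.0298 in dense regions. The sign turned positive without case 4 in the class of 20% to 80% (0.304 points) and in sparse regions (0.0485 points), without case 1 in the former (0.121 points), and without case 2 in the class above 80% (0.0984 points).

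Single CpG cytosines differed within every pair, in both directions. Pair 2 had 40568 cytosines called lower after treatment and 18698 called higher, 1.32% of those tested. Pair 3 had 1815 lower and 7040 higher, pair 5 had 381 and 1724, and pair 6 had 541 and 1155. Pair 4 had 243 lower and 44 higher, and the blood pair, pair 1, had 59 and 29. More were lower than higher in 3 of 6 pairs, and the mean share that was lower was 48.4% ± 28.4 (SD, n = 6; exact two-sided sign-flip test against 50%, p = 0.96875). That share was 52.1% with calls from 10 points up, and above 50% without pair 3, 5 or 6 (54.5% at most). A pair averaged 7268 lower cytosines ± 16326 (SD, n = 6) and 4782 higher ± 7298, and without pair 2 the averages were 608 and 1998. In the RNA of case 2, the median log2 change of epithelial genes was 8.03. Of the 70585 cytosines called in any pair, 49 were lower in 2 pairs, 55 were higher in 2 pairs, 1608 were lower in 1 pair and higher in another, and none went the same way in 3 or more. Pairs 2 and 4 shared 20 lower calls where independent calls would give 2.16, and pairs 2 and 3 shared 9 where these would give 15.4. Between any 2 pairs, shared over expected calls had a median of 0 for lower and 0.433 for higher. Most of these comparisons expected less than 1 shared call, so the medians cannot tell whether calls overlapped less than independent calls would. Of higher calls, pairs 1 and 4 shared 5 (0.000255 expected), pairs 2 and 6 shared 14 (4.60) and pairs 3 and 5 shared 8 (2.21). Pairs 2 and 3 shared 21 higher calls (27.5 expected) and pairs 2 and 5 shared 3 (6.92). No expected number was computed for calls that went opposite ways.

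**Figure D2:**
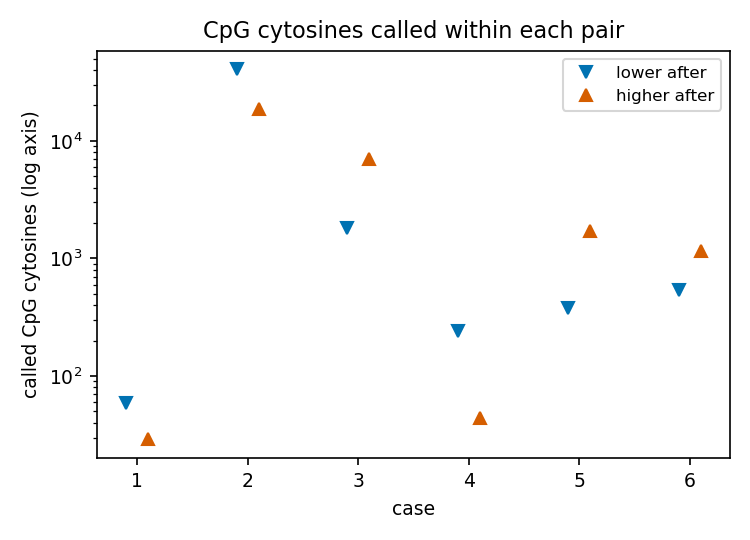
Number of CpG cytosines called within each pair (log axis), lower after treatment (triangles pointing down) or higher (triangles pointing up), for cases 1 to 6. Pair 2 had the most of both kinds, 40568 and 18698, and pairs 3, 5 and 6 had more higher than lower. With calls from 10 points up, not shown, pair 6 had 1360 lower and 1256 higher.

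Regions of 1 kb were tested across the 6 pairs, so that a difference shared by the cases would show. None of the 272001 windows passed in the quasi-binomial model with the case as a block (smallest adjusted p = 0.999998). At an unadjusted p under 0.05, 4752 were lower and 4506 higher, 3.40% of those tested, below the fraction of 0.05 that chance gives. At that level 10176 were lower and 4090 higher without case 3 (smallest adjusted p = 0.917), and 10852 and 4016 without pairs 2 and 3 (0.275), an alternative chosen after the data were seen. The balance went the other way without case 1, the blood pair (3421 lower, 5333 higher), and without case 4 (3550 lower, 5801 higher). More were lower than higher without case 2, 5 or 6, so the direction depended on the case left out. limma on log2 ratios also called 0 windows, with 4748 lower and 4374 higher at that unadjusted level. Without the replicate block, 0 windows passed, with 2019 lower and 2462 higher at that level. Windows that went the same way in all 6 pairs numbered 6701, or 2.46%, where chance gives 3.125%. The median window differed by -0.162 percentage points.

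The second comparison asked which genes and gene groups differed in expression after CC-486 in the tissue of cases 2 to 6. All measured genes of proliferation and of T follicular helper cells and 21 of 27 of the p53 response had lower means after treatment, and 22 of 27 genes of macrophages, 15 of 19 of neutrophils and mast cells and 19 of 19 of keratinocytes had higher means. Of the 28 gene lists with a measured member, 6 were higher and 5 lower after treatment by limma's camera at a preset inter-gene correlation, and 6 and 5 without the replicate block. With an estimated correlation 0 lists passed (smallest adjusted p = 0.4226), and limma's fry, which asks whether a list's genes move on balance one way, also passed 0 (smallest adjusted p = 0.1732), as did its mixed test for change in either direction (smallest adjusted p = 0.7295). At the preset correlation the lower lists numbered 12 without case 3 and 8 without case 6, and all 11 kept their direction with quantile normalization and after the rescaling described below. No single gene of the 14571 tested passed with limma (smallest adjusted p = 0.989875). At an unadjusted p under 0.05, 151 were higher and 409 lower, 3.84% of those tested, below the fraction of 0.05 that chance gives. These 560 genes became 1459 without case 3 (smallest adjusted p = 0.458), 258 without case 4 and 309 without case 5, and none passed. No gene passed without the replicate block (200 at that unadjusted level) or with limma without trend and robust settings (513). Values below are log2 changes in TPM + 1, after minus before, with limma's SE from the fit to 5 pairs. That SE is moderated over all genes, so it differs from the SE of the 5 changes alone. The median change of all tested genes was -0.04, and it shifted by 0.16 when haemoglobin, immunoglobulin and keratin genes were left out and the rest rescaled, an alternative chosen after the data were seen. By case the median of all tested genes was -0.271, -0.119, 0.0946, -0.0453 and 0.115 in cases 2 to 6. List medians by case are given against 0 and were not adjusted for these values.

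Macrophage and monocyte genes were higher as a list, with 22 of 27 members at a higher mean and 5 at a lower mean (camera adjusted p = 4.42e-07; adjusted p = 0.613 with an estimated correlation). Adjusted over the list alone, 5 members passed, and all 5 were higher in 5 of 5 pairs, while 0 passed over all genes. These were FCGR3A, an Fc receptor of monocytes and NK cells (1.81 ± 0.32), SIGLEC1, a sialic acid receptor of tissue macrophages (1.24 ± 0.22), the scavenger receptors MSR1 (1.39 ± 0.28) and CD163 (1.27 ± 0.28), and VSIG4, a complement receptor of tissue macrophages (1.44 ± 0.36). FCGR3A has a near-identical copy, FCGR3B, which neutrophils express. CD68, a lysosomal marker of macrophages, had a change of -0.35 ± 0.49 and was higher in 1 of 5 pairs, and without case 4 its change was 0.073 and without case 3 -0.86. The list's median was above 0 in 3 of 5 cases, and without case 3 its adjusted p was 0.24 and its median change 0.067 in place of 0.40. In case 3 the macrophage median was 1.71, the T-cell lineage median 2.74, the class II median 1.90 and the erythroid median 2.91, and the haemoglobin share of TPM went from 0.169% to 14.8%.

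Neutrophil and mast cell genes were higher as a list (15 of 19 members with a higher mean and 4 with a lower mean, 0 passing alone; camera adjusted p = 6.99e-06; adjusted p = 0.423 with an estimated correlation). Its median was above 0 in 4 of 5 cases, or 5 after the rescaling, and was highest in cases 4 (1.25) and 3 (0.72), where erythroid genes had medians of 4.16 and 2.91. S100A9, an inflammatory protein of myeloid cells, had a change of 1.81 ± 0.46 and was higher in 5 of 5 pairs. The mast cell tryptases TPSAB1 and TPSB2, whose sequences are nearly identical, had changes of 1.34 ± 0.33 and 1.26 ± 0.35. Cytotoxic T and NK cell genes were higher (21 of 28 members with a higher mean and 7 with a lower mean; camera adjusted p = 0.000293; adjusted p = 0.789 with an estimated correlation). FCGR3A alone passed when adjusted over the list alone, and the cytotoxic granule protein GNLY (1.36 ± 0.40) and the NK receptor KLRC1 (1.01 ± 0.38) were higher in 5 of 5 pairs. Case 3 had 3.30 and 2.45 for these genes, and without it they were at 0.87 and 0.65. The cytotoxic list's median was above 0 in 3 of 5 cases, at 2.54 in case 3 and -1.17 in case 2, where T-cell lineage genes had medians of 2.74 and -2.43. After the rescaling it was above 0 in 4 of 5 cases, and without case 3 the list's median change was -0.26 with an adjusted p of 0.631, against 0.33 with all cases and 0.85 without case 2.

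Changes in epithelial, erythroid and fibroblast genes differed by case. Epithelial and keratinocyte genes had a higher mean in 19 of 19 members, with 0 passing alone (camera adjusted p = 1.13e-09; adjusted p = 0.613 with an estimated correlation). Their median change was 8.03 in case 2 and 2.96 in case 5, and between -0.10 and 0.15 in cases 3, 4 and 6. The basal keratins KRT5 and KRT14 were at 0.216 and 0 TPM before treatment in case 2 and at 26175 and 14414 TPM after, and keratin genes held 8.19% of that library's TPM. KRT14 (3.96 ± 2.09), KRT17 (2.31 ± 1.19) and SFN, a 14-3-3 protein of epithelia (2.88 ± 1.55), were the members with the smallest p. Without case 2 these changes were 1.495, 1.001 and 1.012, and the list's median change was 0.75 in place of 1.99. Erythroid and platelet genes were higher in 11 of 12 members and lower in 1, with 0 passing alone (camera adjusted p = 2.31e-05; adjusted p = 0.613 with an estimated correlation). This list's median was above 0 in 3 of 5 cases, and its adjusted p was 0.0814 without case 4, with a median change of 0.94 in place of 1.43. The carbonic anhydrase CA1 had a change of 1.71 ± 0.55, the red-cell anion exchanger SLC4A1 1.40 ± 0.66 and the haemoglobin chaperone AHSP 1.25 ± 0.60, and haemoglobin genes held 14.8% of the TPM after treatment in case 3 and 27.6% in case 4. AHSP was at 0.59 without case 3, and SLC4A1 at 0.83 without case 4. Fibroblast and matrix genes were higher in 17 of 21 members and lower in 4, with 0 passing alone (camera adjusted p = 0.00919; adjusted p = 0.836 with an estimated correlation), with a median of -2.001 in case 3 and above 0 in 4 of 5 cases. FAP, a protease of activated fibroblasts, had a change of 0.59 ± 0.37, the matrix protein THBS2 1.36 ± 0.94 and THY1 -0.61 ± 0.38. FAP was at 0.34 without case 4. THBS2 was at 5.37 in case 2 and its mean was 0.35 without that case and 2.05 without case 3, and THY1 was at -2.21 in case 3 and its mean was -0.21 without that case. The fibroblast list's median change was 0.50, or 1.15, 0.24 and 0.27 without case 3, 4 or 5. The fibroblast list's adjusted p was 0.526 without case 2, 0.083 without case 4, 0.418 without case 5, 0.0513 with no filter on low values and 0.052 after the rescaling. COL1A1, a fibrillar collagen, went from 6135 to 1231 TPM in case 3 and from 85.6 to 710 TPM in case 2.

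Proliferation genes had a lower mean in 39 of 39 members, with 0 passing alone (camera adjusted p = 1.68e-12; adjusted p = 0.613 with an estimated correlation). Their median was -2.06 in case 4, -1.40 in case 5 and -0.73 in case 6, and it was 0.61 in case 2 and 0.05 in case 3. In cases 4 and 5 the medians of fibroblast genes were 1.56 and 1.51, of endothelial genes 0.9996 and 1.227, of adipose and muscle genes 3.12 and 0.57 and of erythroid genes 4.16 and 0.54, and epithelial genes were at 2.96 in case 5. The proliferation list's median change was -0.69, or -0.40 without case 4. The replication factors CDC45 (-1.36 ± 0.37) and MCM2 (-0.77 ± 0.24) were lower in all 5 pairs. CCNE1, the cyclin of S-phase entry, had a change of -1.10 ± 0.40, and MKI67, a marker of cycling cells, -1.003 ± 0.63, each higher in 1 of 5 pairs, and with a case left out MKI67 ran from -1.60 to -0.52. Genes of the p53 and DNA damage response had a lower mean in 21 of 27 members and a higher mean in 6, with 0 passing alone (camera adjusted p = 0.00114; adjusted p = 0.444 with an estimated correlation). This list's median was -0.60, -0.15, -0.33, -0.33 and -0.15 in cases 2 to 6, and after the rescaling the case 3 median was 0.055 and the list's median change -0.10 in place of -0.27. Without case 3 and without the rescaling it was -0.47. GADD45B, a stress-induced gene, had a change of -0.67 ± 0.16, ZMAT3, a p53 target, -0.54 ± 0.15 and TP53INP1, another p53 target, -0.77 ± 0.30.

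T follicular helper genes, which mark the T cells that help B cells and also several PTCL subtypes, had a lower mean in 19 of 19 members, with 0 passing alone (camera adjusted p = 4.16e-06; adjusted p = 0.613 with an estimated correlation). Their median was above 0 in case 3 alone, at 1.02, and was -2.93 in case 2 and between -0.88 and -0.74 in cases 4, 5 and 6. T-cell lineage genes had medians of 2.74 in case 3 and -2.43 in case 2. The list's median change was -0.77, or -0.34 without case 2 and -1.52 without case 3. The B-cell chemokine CXCL13 had a change of -1.55 ± 0.47, GNG4 -1.77 ± 0.55 and the costimulatory receptor TNFRSF4 -1.18 ± 0.50. Follicular dendritic cell genes had a lower mean in 10 of 11 members and a higher mean in 1, with 0 passing alone (camera adjusted p = 0.000333; adjusted p = 0.613 with an estimated correlation), and their median was above 0 in 1 of 5 cases, or 2 after the rescaling. They included CXCL13, the IgE receptor FCER2 (-1.91 ± 0.73, or -1.26 without case 2) and FCAMR, a receptor of IgA and IgM (-1.48 ± 0.46). Immediate-early and stress genes had a lower mean in 20 of 24 members and a higher mean in 4 (camera adjusted p = 0.00114; adjusted p = 0.613 with an estimated correlation). Adjusted over the list alone, 2 of them passed, the transcription factor EGR2 (-1.37 ± 0.26, lower in all 5 pairs) and the heat shock gene HSPA6 (0.97 ± 0.17, higher in 5 of 5 pairs), while NR4A3 had a change of -0.99 ± 0.47, or -0.53 without case 2. The immediate-early list's median was above 0 in 2 of 5 cases, and without case 3 its adjusted p was 0.146 and its median change -0.13 in place of -0.79.

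**Figure D3:**
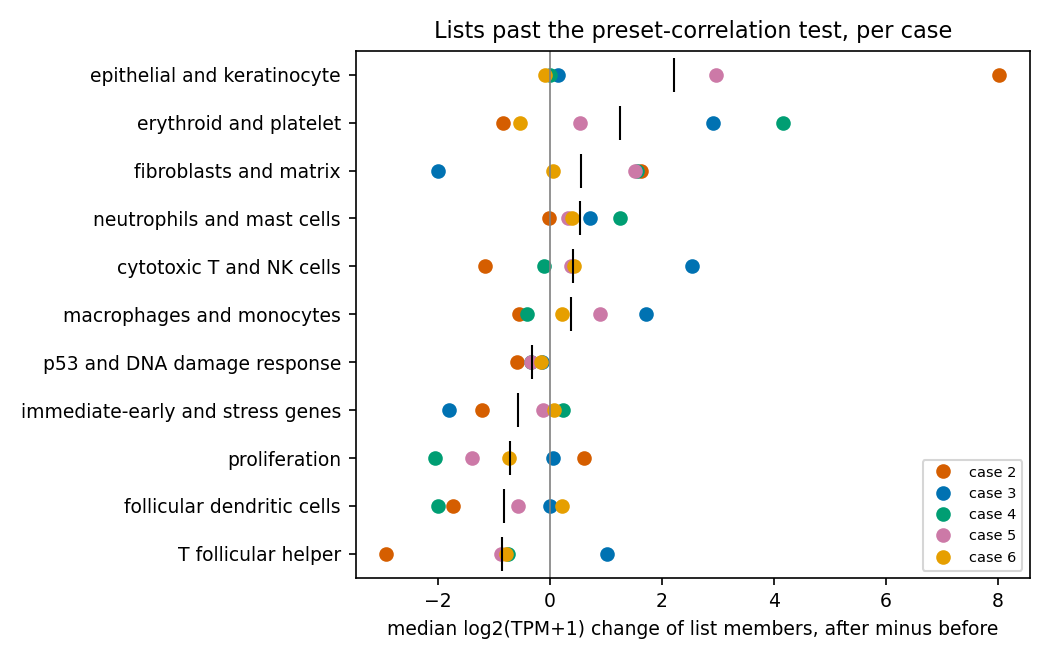
Median log2(TPM + 1) change of the members of each of the 11 lists past the preset-correlation test (horizontal axis, after minus before), with a point per case and a black line at the mean of the 5 cases. The p53 list lies below 0 in all 5 cases, though in case 3 it was at 0.055 after the rescaling, and the epithelial list reaches 8.03 in case 2.

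T-cell, B-cell and other immune lists did not pass with all 5 cases at the main settings, and several passed under an alternative or with a case left out. T-cell lineage genes had a lower mean in 20 of 22 members (camera adjusted p = 0.337), with a median of 2.74 in case 3 and -2.43 in case 2. CD3E, a chain of the T-cell receptor complex, had a change of -0.43 ± 0.70, going from 12.2 to 82.1 TPM in case 3 and from 173 to 24.7 TPM in case 2, and without case 2 its change was 0.15 and without case 3 -1.20. MS4A1, which encodes the B-cell antigen CD20, had a change of -0.66 ± 0.71, or 0.20 without case 2 and -1.12 without case 3. B-cell genes had a lower mean in 18 of 25 members (adjusted p = 0.0788), plasma cell genes a higher mean in 13 of 20 (0.153), dendritic cell genes a lower mean in 12 of 19 (0.176) and genes of regulatory T cells and checkpoints a lower mean in 9 of 13 (0.391). Genes of antigen presentation by class I had a lower mean in 15 of 17 members (0.165), and those of class II in 7 of 14 (0.783), where camera's direction was up against a median of -0.0039 and a mean of -0.0165. Inflammatory cytokines and chemokines had a lower mean in 16 of 19 members (0.082), and NFKBIA, an inhibitor of NF-kB that belongs to that list, had a change of -0.86 ± 0.24. Endothelial genes had a lower mean in 12 of 21 members (0.822), where camera's direction was up against a median of -0.0363 and a mean of -0.0395, and adipose and muscle genes had a higher mean in 11 of 14 (0.0788). After the rescaling the B-cell, inflammatory, dendritic and T-cell lineage lists passed as lower (adjusted p = 0.000203, 0.00457, 0.0173 and 0.0359), as did the inflammatory list with quantile normalization (0.0306), and 0 lists passed in any setting with an estimated correlation. Without case 3 the T-cell lineage (adjusted p = 6.08e-10), B-cell (0.000171), regulatory T-cell (0.000209), class II (0.000716), class I (0.00186), dendritic (0.0135) and inflammatory (0.0485) lists passed as lower, and the endothelial and adipose and muscle lists as higher (0.00301 each). Class I genes passed as lower without case 2 (0.0463). Without case 4 plasma cell (3.4e-06) and class II (0.00265) genes passed as higher. Without case 5 the inflammatory (0.0199) and endothelial (0.0488) lists passed as lower. Without case 6 the B-cell (0.00439), inflammatory (0.0421) and dendritic (0.0481) lists passed as lower, and the adipose and muscle (0.0279) and plasma cell (0.0452) lists as higher. B-cell genes also passed as lower with no filter on low values (0.0475) and with protein-coding symbols alone (0.0261), and at a minimum mean of 5 TPM dendritic genes passed as lower (0.0167) and plasma cell genes as higher (0.0411). Medians turned without case 2 for the T-cell lineage (0.365), B-cell (0.14), regulatory T-cell (0.106), class II (0.103) and endothelial (0.174) lists, and without case 3 for plasma cells (-0.13) and endothelium (0.564). They also turned without case 4 for class I (0.0123), class II (0.325) and adipose and muscle (-0.522), and without case 5 for class I (0.0635) and class II (0.0334). The rescaling shifted nearly all genes alike, to a median of 0.13 over all genes, and by that shift the class I median was 0.0515 and the class II and endothelial medians 0.175 and 0.136, and the class II median was also above 0, at 0.0713, with quantile normalization.

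Genes that the drug acts on or through did not pass as lists with all 5 cases at the main settings, and some passed under alternatives. Genes of the DNA methylation machinery had a lower mean in 17 of 25 members (camera adjusted p = 0.416). DNMT1, the maintenance methyltransferase and a direct target of the drug, had a change of -0.18 ± 0.19, and the de novo enzymes DNMT3A and DNMT3B had changes of -0.12 ± 0.30 and 0.24 ± 0.29. With a case left out the changes ran from -0.30 to -0.042 for DNMT1 and from 0.12 to 0.48 for DNMT3B. The log2 change of DNMT3A was 0.191 without case 2, -0.28 without case 3 and 0.0559 after the rescaling. UHRF1, which brings DNMT1 to replicated DNA, had a change of -0.60 ± 0.51, and TET2, which oxidises methylcytosine, -0.21 ± 0.19, and these ran from -1.09 to -0.24 and from -0.34 to -0.080 with a case left out. Genes of azacitidine uptake and metabolism had a lower mean in 13 of 19 members (adjusted p = 0.0788), and the list passed as lower at a minimum mean of 5 TPM (0.0344) and without case 2 (0.0463). Without pairs 2 and 3 this list and that of the methylation machinery passed as lower (0.0115 and 0.0276). Interferon-stimulated genes were split, with 19 members at a higher mean and 20 at a lower mean, and camera's direction was up against a median of -0.00448 and a mean of 0.0606 (adjusted p = 0.186). That adjusted p was 0.00354 without case 4, 0.0418 with quantile normalization and 0.0452 after the rescaling, where the list passed as higher, and with an estimated correlation it was 0.836. ISG15, a ubiquitin-like protein induced by interferon, had a change of -0.37 ± 0.26, which ran from -0.60 without case 6 to -0.18 without case 4. Genes of cytosolic nucleic-acid sensing had a lower mean in 17 of 25 members (0.890) and passed as lower without case 3 (0.0205), and endogenous retroviral genes a higher mean in 2 of 2 (0.743). Germline and cancer-testis genes, often silenced by methylation, had 7 of 45 members measured, 3 with a higher and 4 with a lower mean (0.326), and camera's direction was up against a median of -0.0076 and a mean of 0.123. Tumour suppressors with reported promoter methylation had a lower mean in 14 of 25 members (0.884), with camera's direction down against a mean of 0.0098 and a median of -0.0322. The medians of the methylation machinery (0.0795), azacitidine metabolism (0.0372), sensing (0.118), interferon (0.169), germline (0.0947) and tumour suppressor (0.144) lists were above 0 after the rescaling, by a shift that nearly all genes shared and that put the median of all genes at 0.13. With quantile normalization those of the sensing (0.0178), interferon (0.0234) and tumour suppressor (0.0161) lists were above 0, and the endogenous retroviral median was -0.091. With a case left out, medians turned for interferon (0.044, 0.0165 and 0.0418 without case 2, 4 or 5), germline (0.246 and 0.146 without case 2 or 3), tumour suppressor (0.156 without case 3), sensing (0.158 without case 2) and endogenous retroviral (-0.0467 without case 4) genes. The germline median was also above 0, at 0.0042, with no filter on low values.

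The genes with the smallest p among those that moved one way in all 5 pairs did not pass (limma adjusted p = 0.99 for each). Besides FCGR3A, HSPA6, SIGLEC1, MSR1, CD163 and TPSAB1, those with a higher mean were the neutrophil defensin DEFA3 (1.53 ± 0.31), the BMP antagonist GREM1 (1.10 ± 0.24), ADAP2 (0.72 ± 0.17) and DZIP1L (0.98 ± 0.24). DEFA3 and HSPA6 have near-identical copies in the genome, so their reads cannot be assigned with certainty. Besides EGR2, those with a lower mean were the T-cell membrane protein ITM2A (-1.38 ± 0.19), the tryptophanyl-tRNA synthetase WARS (-0.96 ± 0.19), the branched-chain aminotransferase BCAT1 (-1.19 ± 0.24) and LIMS1, an adhesion adaptor (-0.93 ± 0.21). The other 5 were OVCA2 (-1.31 ± 0.24), the mitochondrial ribosomal gene MRPL53 (-1.38 ± 0.31), KIAA1524, an inhibitor of the phosphatase PP2A (-1.04 ± 0.23), NAA60 (-0.69 ± 0.16) and FAM107B (-0.92 ± 0.21). In all, 303 genes were higher and 727 lower in all 5 pairs, 7.07% of those tested, where chance gives 6.25%.

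**Figure D4:**
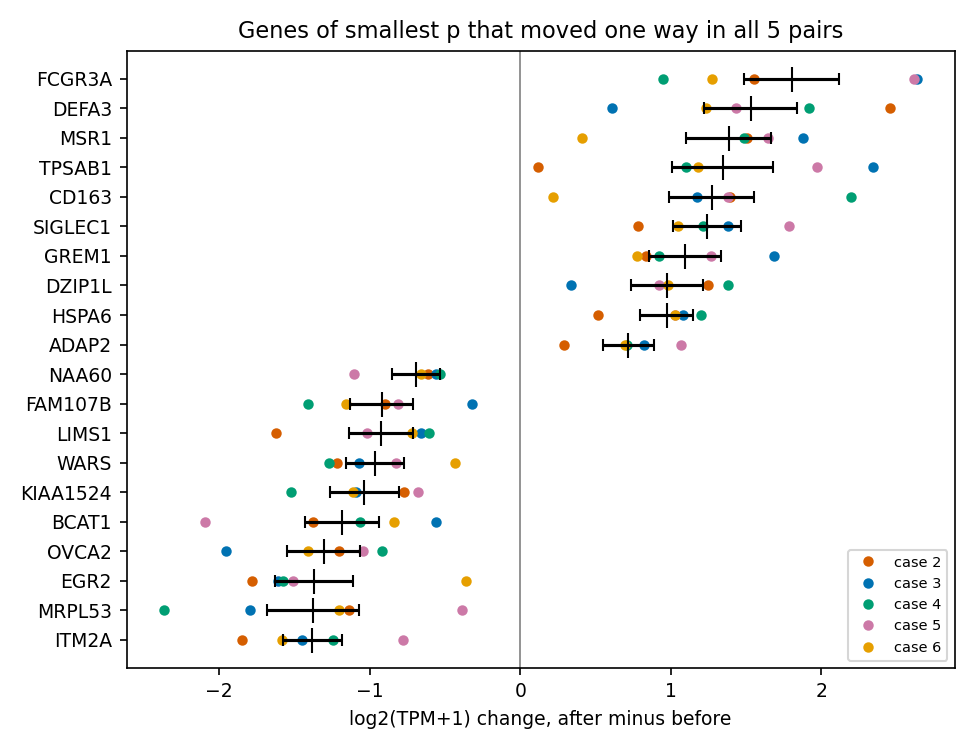
Log2(TPM + 1) change, after minus before, of the 20 genes of smallest p that moved one way in all 5 pairs (horizontal axis). Each case has a point, and the mean of 5 pairs with limma's moderated SE is in black. FCGR3A had the highest mean, 1.81, and ITM2A the lowest, -1.38, and none of the 20 passed after adjustment.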

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

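The tests of epithelial cells in pair 2, of strand disagreement and of cell makeup below were chosen after the result was seen, and the thinning of reads and the rescaling without haemoglobin, immunoglobulin and keratin genes were added after the data were seen. Of 99 groups of samples examined, 11 (11.1%) held a sample far from the rest, where chance gives about 1 in 20.

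Pair 2 had 40568 cytosines called lower after treatment, against 1815 in the next pair. A difference in read depth was argued against as the whole cause, since with both libraries thinned to 20 reads per site pair 2 still had 368 calls against 1 in the next pair. Thinning evens out reads and not the molecules behind them, so it speaks to read depth alone. Loss of methylation from the drug stays open: 68.5% of the calls were lower, under the bound of 75% set against it, but that share moved with depth, and at 20 reads 312 calls were lower and 56 higher, a share of 84.8%. Epithelial cells in the second biopsy are another candidate explanation: the epithelial list had a median log2 change of 8.03 in the RNA of that pair, with KRT5 and KRT14 at 26175 and 14414 TPM. The list was fixed as markers of cells a biopsy can hold, the RNA and DNA need not come from the same piece of tissue, and no epithelial methylation profile was compared.

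The 11 lists past the preset-correlation test could reflect chance. Among the 16 ways to name the libraries within the pairs, the real one included, 11 gave as many lists (real 11, highest other 19). These are too few ways for a share under 0.05, but the real count was not high among them, so chance cannot be excluded. Of 100 drawn splits of the 10 libraries, 67 gave as many lists (real 11, highest other 20). Most of these drawn splits parted only 1 or 3 pairs. With the case as a block their counts rest on those pairs and are not comparable with the real count, so they decide nothing about chance. A few genes taking most of the TPM stays open: 10 of the 11 lists passed in the same direction after haemoglobin, immunoglobulin and keratin genes were left out, but the rescaling shifted genes nearly alike (median 0.17, interquartile range 0.027 on the log2 scale), and camera compares a list with the other genes, so this could not decide. Different cell makeup of the biopsies of a case stays open and cannot be told apart from an effect of treatment: the SD of the list medians across cases was 1.89 times their mean size, short of the bound of 2 set for it. An effect of the drug that the cases share stays open too, and was not tested against untreated biopsies.

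At 12.1% of CpGs read on both strands the strands differed by over 20 points, and at 8.82% by over 50 points, with medians of 3.81% on the lower strand and 89.7% on the higher. A variant or methylation of 1 strand in single cases was argued against, since of the 130405 CpGs whose strands were over 50 points apart in at least 1 case, 96.7% disagreed the same way in all 6 cases, though it stays open for the rest. Unmethylated bases filled in at the ends of restriction fragments may be the source: of the CpGs low on the reverse strand with another within 100 bp, 99.8% were followed by one low on the forward strand.

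Other splits of the libraries were also counted for the results of 0 windows and 0 genes. With a real count of 0 each split gives as many by construction, so the 100 drawn splits of the methylation libraries (highest other 246) and the 100 of the RNA libraries (highest other 574) decide nothing about chance. The RNA splits with 574 genes parted 1 pair, so that with the case as a block their calls rest on that pair, and with every pair parted the 32 ways for windows and the 16 for genes gave 0 calls.

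The keratin share of TPM was 8.19% in case 2 after treatment, where the next library had 0.121%. Before treatment it was 0.0449% in case 3, where the next had 0.0105%. The haemoglobin share before treatment was 0.922% in case 5, where the next had 0.242%. Log2 changes that stood apart from the other cases were 0.52 for HSPA6 and -4.06 for MS4A1 in case 2, 3.30 for GNLY in case 3, -1.10 for NAA60 in case 5, and 0.41 for MSR1 and -0.36 for EGR2 in case 6. The median of the germline and cancer-testis list was -0.58 in case 2, where the nearest was 0.18. The pooled methylation level of the mitochondrial genome, which no comparison used, was 1.46% after treatment in case 5, where the highest before treatment was 0.656%.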

How the results depend on the processing

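Of 1094 values under alternatives, counts and means stayed on their side in 150, moved in 11 and reversed in 9. Lists stayed in 142, weakened in 22 and reversed in 1. Genes stayed in 753 and reversed in 6. Part of this was fixed in advance. A gene that moved one way in all 5 pairs cannot reverse with a case left out. Log2 changes are the same without the replicate block or the trend and robust settings. Counts of 0 windows or genes that stayed at 0 are among the 150. These tallies therefore do not measure how firm the results are. Mean methylation, windows (0) and genes (0) gave the same result without the replicate block, as did lists (6 higher, 5 lower). The cause of the changes below was not tested, except that fewer cases were used where cases are left out.

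The mean methylation difference reversed to 0.132 points with pooled reads, and was -0.418 to -0.0579 with a case left out. Leaving out each case gave -0.538 to 0.304 points in the class of 20% to 80%, -0.729 to 0.0984 above 80% and -0.402 to 0.0485 in sparse regions. The mean share of lower cytosines was 52.1% at 10 points and 41.2% to 54.5% with a case left out. The mean numbers were 52 lower and 9.5 higher when thinned to 20 reads, and 608 to 8710 lower and 1998 to 5732 higher with a case left out.

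With an estimated correlation 0 lists were higher and 0 lower. Leaving out each case gave 5 to 12 lower lists (12 without case 3, 8 without case 6), log2 changes of -0.28 to 0.19 for DNMT3A, -1.20 to 0.15 for CD3E, -1.12 to 0.20 for MS4A1 and -0.86 to 0.073 for CD68, and a cytotoxic list median of -0.26 to 0.85. After the rescaling 9 lists were lower and the log2 change of DNMT3A was 0.0559. Without pairs 2 and 3, chosen after the data were seen, 1 gene was higher (RGPD5, which has near-identical copies, at 2.90 with an adjusted p of 0.0144, against 1.23 and 0.99 with all cases), 13 lists were lower, 8 of the 11 lists passed in the same direction among 19 that passed, and the log2 change of DNMT3A was 0.0817. Of 14 settings other than the estimated correlation, the proliferation, p53, T follicular helper, follicular dendritic, neutrophil and epithelial lists passed in all, erythroid in 13, macrophage, cytotoxic and immediate-early in 12, and fibroblast in 9.

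Promoter methylation against expression and annotation classes were not run. With RNA depth unknown, small changes in genes of low TPM cannot be weighed against counting error, and thinning to 20 reads left at most 1 call in pairs other than pair 2.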

Other observations

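Lists that did not pass held single members with the same sign in all 5 pairs, which did not pass either and were chosen after their values were seen. DCTD, a deaminase of deoxycytidylate, had a log2 change of -0.43 ± 0.19 (limma's moderated SE, 5 pairs). TDG, a glycosylase that removes oxidised methylcytosine, had -0.59 ± 0.20, and HERC6, an interferon-induced gene, 0.42 ± 0.21.

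Changes were weakly correlated between cases. The correlation of methylation changes across CpG cytosines between 2 cases was -0.152 to 0.0754 (median -0.0081), and of expression changes across genes -0.305 to 0.430 (median 0.0528), where cytosines and genes are not independent replicates. Changes of over 2 on the log2 scale were found in 1604 genes in case 2 and 1364 in case 3, and in 331, 338 and 46 genes in cases 4, 5 and 6. Immunoglobulin genes held 19.3% of the TPM before treatment in case 4 and 5.20% after, and 2.22% and 1.85% in case 6. Their share was higher after treatment in the other cases, from 2.95% to 6.37% in case 2, from 0.306% to 8.97% in case 3 and from 1.95% to 5.21% in case 5.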
